A study of Homo sapiens with 10 samples.

How the data were processed

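Total RNA of 10 samples of UT-SCC-12a cells, 5 with stable miR-23b-3p overexpression and 5 with a scrambled RNA, was hybridized to Affymetrix human gene arrays with biotin-labelled cDNA, per the labels' protocols. Groups and replicate numbers came from the sample titles. The deposited log2 values of the series value table, given to 2 decimals, were used as they stand; they are RMA values, per the submitters' processing notes, and the header of the authors' whole-series table names RMA background correction, quantile normalization and median polish. Transcriptome Analysis Console is also named in the submitters' processing notes, without a version. Fold change columns in the authors' table are signed linear ratios, per the file headers. The authors' fold of B over A equalled the ratio of mean linear values, overexpressing over control, for 53617 of 53617 probe sets at a relative tolerance of 0.001, and the inverse ratio for 590, which fixed the log base and the direction. The p-values and q-values of the authors' table come from Student's t-test, per the file headers; the adjustment behind q is not given in the sources used here. The authors' table also has 10 columns of values per array whose names match no sample label, and they were not used. Its mean intensity columns, deposited under the letters A and B, name no group either; after a first check of direction on them they were replaced by the fold column and are not used.

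The annotation columns of the authors' table (NetAffx build 36, hg19, per the file headers) gave symbols, coordinates, probe set categories and cross-hybridization types. Of 53617 probe sets, 48144 gene-level probe sets were tested, 44629 of the main category and 3515 rescue probe sets, and 5473 control and reporter probe sets were left out; this reads the planned phrase on array controls in that way. A single symbol was given for 31135 of the tested probe sets and none for 17009. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCh38.p14, used for names only, for 29774 probe sets, and kept as in the file for 1361. Where a gene had several probe sets, the one with the highest mean over all arrays stood for it in the lists; 34 list genes had several, and in 17 of these the probe sets differed in sign, in 0 with p under 0.05 on both sides. No arrays were duplicates, since any pair shared at most 2.26% of identical values.

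The comparison, overexpressing minus control, was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 10 arrays without covariates, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. SE is the moderated standard error of limma, and every adjusted p of a gene is limma's unless another test is named. Genes named by the plan, RRAS2 and the miR-23b locus, also had an exact two-sided permutation test over the 252 ways to choose 5 of 10 arrays. The 34 gene lists, the tests and the naming rule were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, Benjamini-Hochberg over the 34 lists, and again with an estimated correlation and with fry. Of the lists' genes, those without a probe set under their symbol were left out, for example PECAM1 and NDUFA4. A score per array was the mean over a list's members of their deviation from the mean of all arrays.

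Named genes were RRAS2 and the miR-23b locus; up to 10 rises and 10 falls with the largest change among probe sets past the threshold with 1 symbol and groups that do not overlap; and up to 4 members of each list with the smallest adjusted p, or 2 where no member passed. Passing was read as passing over all genes or over the list alone, a reading chosen after list values had been seen. CCL2, PTGS2, MYC, CCND1, CDH1, CCN1 and CCN2 fall outside that rule and were added after their values were seen, as were the genes quoted from the authors' table. An item that the rule selects is not reported here.

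Alternatives were a replicate block, other variance priors, a filter on the dimmest 25% of probe sets (mean log2 value up to 2.475), median centring, renewed quantile normalization, array weights, a stricter threshold of 0.01, Welch's test, probe sets with a symbol only and leaving out each array. Student's test as named by the header, a restriction to cross-hybridization type 1, a poly-A spike covariate, the NRF2 list without AKR1 genes and annotation terms were added after seeing the data. The search for seed sites in 3 prime untranslated regions needs transcript sequences and was not run here.

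The fit was tested on simulated arrays with 48144 probe sets, 5 against 5, drawn with the means and spreads of this comparison. Changes were placed only in probe sets with a mean log2 value above 5, 12131 of the 48144. Their median residual SD was 0.109, against 0.146 over all probe sets, and recovery in dimmer ones was not simulated. Above that level the fit recovered 30.8% of simulated changes of 1.25-fold, 82.1% of 1.5-fold and 96.7% of 2-fold, and 5.43% of its calls were false. Camera, run on 29403 simulated genes, called 100% of lists of 28 genes shifted by 0.1 and 0 of 150 unshifted lists. The simulated genes were independent and their lists random, so 0 of 150 gives no false-call rate for lists of correlated genes. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.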

Results

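UT-SCC-12a is an established line of human cutaneous squamous cell carcinoma, a keratinocyte cancer of the skin. Stable lines carried a lentiviral construct for the microRNA miR-23b-3p or for a scrambled RNA, and their total RNA was read on Affymetrix human gene arrays, 5 arrays per group. The series title places the question on RRAS2, a RAS-related GTPase, as the microRNA's target. Median log2 values per array lay between 3.14 and 3.19, and any 2 arrays of a group correlated across probe sets with r between 0.991 and 0.994. The labels do not say that the 5 RNA samples of a group came from separate cultures, so p-values measure only the spread between these arrays, and their number limits the precision. The poly-A spikes, bacterial RNAs added to follow labelling, read 5.35 ± 0.093 (SD) with miR-23b-3p and 5.46 ± 0.020 in controls, by an exact two-sided permutation test p = 0.0238, the lowest p of 8 array measures checked.

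RRAS2 (hg19 chromosome 11, 14299466 to 14386052, minus strand) stood at 6.22 ± 0.084 (SD, n = 5) in the overexpressing cells and at 6.40 ± 0.063 (n = 5) in the controls, a log2 difference of -0.18 (SE 0.063) or 1.13-fold less. The overexpressing arrays lay between 6.10 and 6.33 and the control arrays between 6.34 and 6.49, so the groups did not overlap. The exact two-sided permutation p of RRAS2 was 0.00794, the smallest that 5 against 5 arrays can give. After Benjamini-Hochberg adjustment over the 6 probe sets of genes named by the plan it was 0.0476. RRAS2 alone was that low, so this value follows from the number of probe sets counted, and counting more could raise it. Over all 48144 probe sets tested, limma gave RRAS2 an unadjusted p of 0.0145 and an adjusted p of 0.665, so it did not pass the genome-wide threshold of 0.05. In the authors' deposited table RRAS2 has a fold change of -1.13 with p = 0.00480 and q = 0.473. Groups were as fully apart in 648 of the tested probe sets, 1.35% where chance gives 0.794%.

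No probe set of the microRNA's own locus on chromosome 9 passed the threshold. The MIR23B probe set, which covers the hairpin from 97847490 to 97847586, stood at 6.43 ± 0.20 (SD, n = 5) in overexpressing cells and 6.21 ± 0.22 in controls, a difference of 0.22 (SE 0.12) with an exact permutation p of 0.159. The neighbouring hairpin MIR27B differed by 0.15 (SE 0.16). The 3 probe sets of the host gene AOPEP differed by 0.16, 0.21 and -0.32, and none passed. Whether any of these probes can see the lentiviral transcript is not given in the sources used here, and MIR24-1 was not analysed here.

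LY6D, a keratinocyte surface protein, fell by 0.79 on the log2 scale (SE 0.087) and was 1.73-fold less abundant in miR-23b-3p cells. MMP1, the interstitial collagenase, fell by 0.70 (SE 0.074), and CXCL8, the neutrophil chemokine interleukin 8, fell by 0.69 (SE 0.069). The T-cadherin gene CDH13 fell by 0.63 (SE 0.085), the ERBB ligand NRG1 by 0.61 (SE 0.081) and the annexin ANXA10 by 0.52 (SE 0.056). VTCN1, which encodes the immune checkpoint ligand B7-H4, rose by 0.72 (SE 0.097), 1.65-fold. At the probe set whose change is given for each of these 7 genes, the 5 arrays of one group lay entirely to one side of the other 5. In the authors' deposited table a further NRG1 probe set has a fold change of only -1.01, against -1.525 for the one given here. The fall of NRG1 was thus not shared by all of its probe sets.

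With limma, 9 of 48144 probe sets passed an adjusted p of 0.05, 7 lower and 2 higher, and 8 of them changed at least 1.5-fold, ANXA10 at 1.43-fold being the exception. Adjusted p was 0.00686 for CXCL8, 0.00748 for MMP1, ANXA10 and LY6D, 0.0398 for NRG1 and VTCN1, and 0.0406 for CDH13. The largest change of all belonged to an intergenic long noncoding RNA without a symbol (probe set 16922795, chromosome 21, 40218171 to 40220568), which stood at 5.32 ± 0.26 (SD, n = 5) in controls and 3.76 ± 0.14 in overexpressing cells and fell by 1.55 (SE 0.12, limma adjusted p = 0.000619). The other unnamed call, a noncoding transcript of 8 probes with a mixed cross-hybridization type (probe set 16673840, chromosome 1, 171783652 to 171783766), rose by 0.98 (SE 0.13, limma adjusted p = 0.0385). Probe set 16673840 in controls and 16922795 in overexpressing cells lie near the antigenomic background of 3.37 to 3.40, so the size of these changes is uncertain. Both unnamed probe sets lie outside the naming rule and were picked after their values were seen. At an unadjusted p under 0.05 there were 3191 probe sets, 1769 higher and 1422 lower, against 2407.2 expected at random, but of 100 splits of the 10 arrays into 5 and 5 the labelled one and 2 others reached as many, the highest 3323. In the authors' deposited table, 4 probe sets have q under 0.05: ANXA10 at a fold of -1.43, PTBP2 at -1.19, PLSCR5 at -1.12 and FN1 at 1.23.

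**Figure D1:**
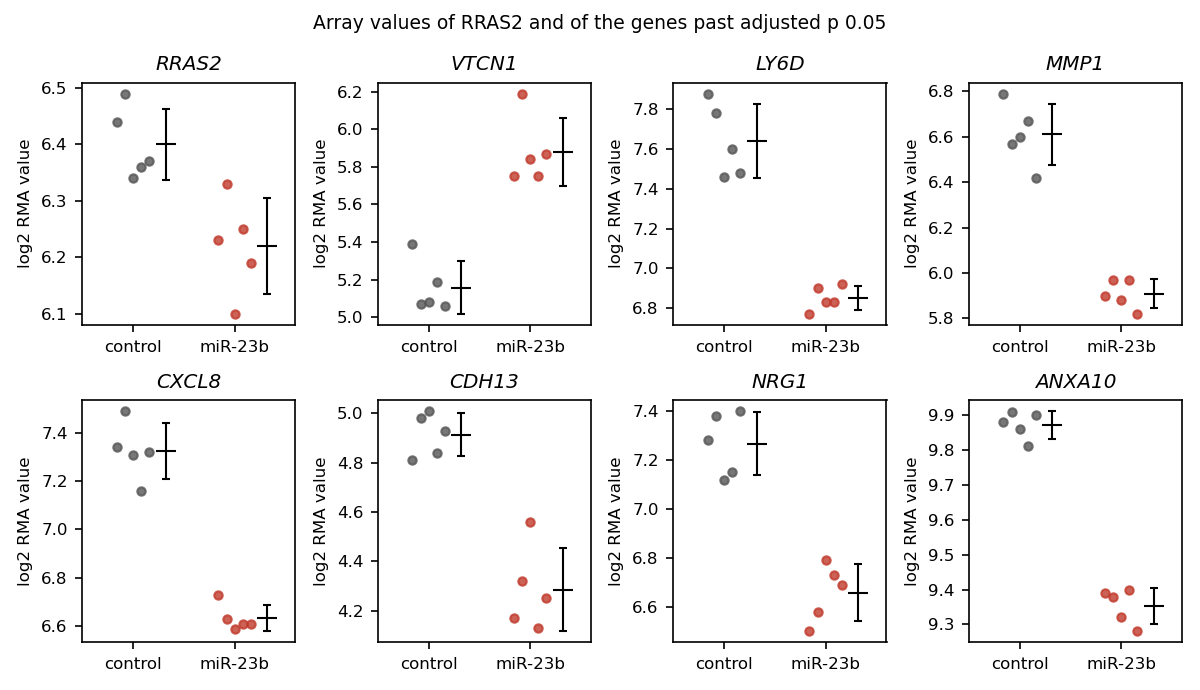
Log2 RMA values (vertical axes, each on its own scale) of RRAS2 and the 7 named genes past the limma threshold, by group; dots are single arrays, and bars show mean and SD of 5 arrays. The RRAS2 arrays span 6.10 to 6.49 in all, while CXCL8 drops from 7.32 to 6.63 and VTCN1 climbs from 5.16 to 5.88.

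Calls for LY6D, MMP1, CXCL8, ANXA10 and the chromosome 21 transcript held without any single array, but 4 of these 5, all except ANXA10, were not called when each gene's own variance in each group replaced limma's moderated one. NRG1 missed the threshold in 10 of 10 fits without a single array (adjusted p 0.0558 to 0.172), CDH13 in 9 (up to 0.176), VTCN1 in 8 (up to 0.172) and probe set 16673840 in 8 (up to 0.153). With the poly-A spike mean of each array as a covariate, 2 probe sets were called, of which 1, the chromosome 21 transcript, was among the 9, while standard errors grew to between 1.37 and 1.43 times their size and the changes stayed near their size, at -0.78 for MMP1, -0.71 for CXCL8, -0.57 for ANXA10, -0.79 for LY6D, 0.79 for VTCN1, -0.64 for NRG1 and -0.55 for CDH13 (adjusted p 0.0880 to 0.482).

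Inflammatory genes fell as a list. Of 28 measured members of the NF-kB and inflammation list, 19 were lower and 8 higher, with a median change of -0.071 (camera adjusted p = 0.000161; adjusted p = 0.0599 with an estimated correlation). Only CXCL8 passed over all genes, and 5 members passed when adjusted over the list alone, all lower: CXCL8, the interleukin 1 genes IL1A at -0.33 (SE 0.080) and IL1B at -0.33 (SE 0.083), TNFAIP2 at -0.22 (SE 0.056) and the chemokine gene CCL2. CCL2 sits near background at a mean level of 2.38, and 11 of the 28 members lay under a level of 4. PTGS2, the inducible prostaglandin synthase, went the other way at 0.12 (SE 0.064) without passing.

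Transcripts that follow ERK signalling also fell as a list, 18 of 24 lower with a median of -0.071 (camera adjusted p = 0.000534; adjusted p = 0.0599 with an estimated correlation). EREG, an EGF receptor ligand, stood at -0.51 (SE 0.073) and HBEGF, another, at -0.29 (SE 0.082), and these 2 passed adjusted over the list alone, at 0.000321 and 0.0447, while 0 members passed over all genes. EREG was just short of the genome-wide threshold at 0.0644 and passed it under 4 of the alternative settings, with adjusted p from 0.00314 to 0.0455. The AP-1 subunit gene FOSL1 at -0.22 (SE 0.079) and the feedback inhibitor SPRY4 at -0.18 (SE 0.066) did not pass. MYC at 0.086 and CCND1 at -0.048 were within 2 standard errors of 0.

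Epithelial junction genes rose together, by the smallest p of the 34 lists. Of 30 members 27 were higher, with a median change of 0.09 (camera adjusted p = 4.1e-05; adjusted p = 0.0599 with an estimated correlation). The tight junction gene CLDN4 stood at 0.28 (SE 0.080) and the epithelial transcription factor GRHL1 at 0.24 (SE 0.070), and 0 members passed alone, over all genes or over the list. E-cadherin, CDH1, was at 0.082 (SE 0.058). YAP targets rose too, 19 of 24 higher with a median of 0.072 (camera adjusted p = 0.00396; adjusted p = 0.342 with an estimated correlation). There the stress gene GADD45B at 0.39 (SE 0.078) and the ectonucleotidase gene NT5E at 0.26 (SE 0.066) passed over the list alone, CRIM1 and AMOTL1 stood at 0.18 each without passing, and the best-known targets CCN1 and CCN2 were at 0.052 each.

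Cell cycle, ribosome and respiration lists passed camera at its preset correlation but not with an estimated one. Mitosis and G2/M genes rose by a median of 0.044, 30 of 39 higher (camera adjusted p = 0.0320; adjusted p = 0.675 with an estimated correlation), with NEK2 at 0.13 (SE 0.054) and AURKB at 0.17 (SE 0.078). The mitosis list missed the threshold in 5 of 10 fits without a single array (adjusted p up to 0.156), and the score of overexpressing replicate 1, at -0.0345, lay below 4 of the 5 control scores. DNA replication and G1/S genes fell by a median of 0.046, 27 of 40 lower (camera adjusted p = 0.00666; adjusted p = 0.344 with an estimated correlation), with GINS4 at -0.28 (SE 0.088) and FEN1 at -0.16 (SE 0.062). Ribosomal protein genes fell as well, 29 of 36 lower at a median of -0.043 (camera adjusted p = 0.00612; adjusted p = 0.342 with an estimated correlation), as did oxidative phosphorylation genes, 25 of 32 lower at a median of -0.052 (camera adjusted p = 0.0318; adjusted p = 0.202 with an estimated correlation). SDHC at -0.20 (SE 0.071) led the latter and RPS18 at -0.12 (SE 0.063) the former. In these 4 lists 0 members passed alone.

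NRF2 targets, the antioxidant and detoxification genes, fell as a list, 21 of 26 lower with a median of -0.043 (camera adjusted p = 0.0269; adjusted p = 0.174 with an estimated correlation). The aldo-keto reductases AKR1B10 at -0.58 (SE 0.17) and AKR1C2 at -0.49 (SE 0.18; level 3.41, near background) had the largest differences, 0 members passed alone, and without the 4 AKR1 genes the list's adjusted p was 0.283. Interferon-stimulated genes rose by a median of 0.05, 27 of 35 higher (camera adjusted p = 0.0320; adjusted p = 0.730 with an estimated correlation), with the RNA sensor IFIH1 at 0.17 (SE 0.057) and IFI6 at 0.20 (SE 0.084), and 0 members passed. Without overexpressing replicate 1 the interferon list's adjusted p was 0.889.

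**Figure D2:**
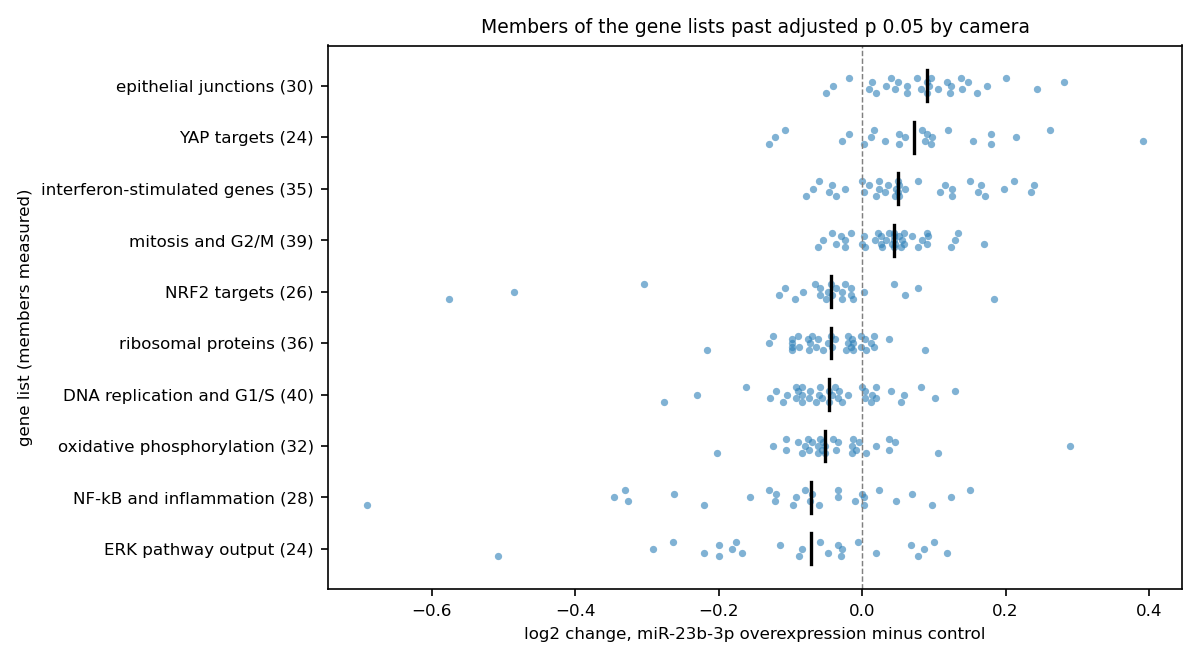
Log2 change of each member (dots; horizontal axis, miR-23b-3p minus control) in the 10 gene lists past the camera threshold (vertical axis, members measured in brackets), with the list median as a black bar. Medians run from -0.071 for ERK output and NF-kB to 0.09 for epithelial junctions, and single members such as CXCL8 at -0.69 and GADD45B at 0.39 lie far from them.

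In all, 10 of 34 lists passed with camera at its preset correlation, 4 higher and 6 lower, while 0 passed with an estimated correlation and 3 (epithelial junctions, NF-kB and ERK output) passed fry, which tests whether a list's genes move one way. The poly-A spike value as a covariate left 4 of the 10, namely these 3 and the YAP targets. By an exact permutation test of the scores per array, 0 lists passed after Benjamini-Hochberg adjustment. The lowest adjusted p of that test was 0.0675, shared by epithelial junctions, NF-kB, ERK output and NRF2 targets. Their unadjusted exact permutation p was 0.00794 each, the smallest that this test can give. Their miss of the adjusted threshold is therefore a limit of the test and no evidence against these lists.

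The remaining 24 lists did not pass. Reported miR-23 targets had a median of -0.021, 23 of 36 lower (camera adjusted p = 0.126; 0.553 with an estimated correlation), with the actin regulator MTSS1 at -0.26 (SE 0.069) and the proline dehydrogenase PRODH at -0.25 (SE 0.080), and 0 members passed. Within the RAS family and effectors (adjusted p = 0.694) NRAS was higher, at 0.35 (SE 0.070) and 0.00998 adjusted over the list alone against 0.252 over all genes, while HRAS stood at -0.18 (SE 0.094) and RASA1 at -0.14 (SE 0.069). Proteases and invasion genes (adjusted p = 0.455) held the called MMP1, and TIMP2, an inhibitor of metalloproteinases, passed over the list alone at 0.22 (SE 0.056). MMP13 at -0.29 (SE 0.099) and TIMP1 at -0.17 (SE 0.058) did not. In the mesenchymal list (adjusted p = 0.783) fibronectin, FN1, stood at 0.29 (SE 0.054) and N-cadherin, CDH2, at -0.27 (SE 0.058), each past the threshold over the list alone, with TPM2 at 0.30 not past it.

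Keratinocyte lists gave no call at the threshold. Basal keratinocyte genes had 15 of 20 members lower at a median of -0.049 (adjusted p = 0.0511), led by KRT6A at -0.21 (SE 0.093) and SOX2 at -0.17 (SE 0.082). Differentiation genes (adjusted p = 0.694) had 16 higher and 21 lower, with S100A7 at 0.23 (SE 0.083) and KRT1 at -0.22 (SE 0.085), and 21 of those 37 members lay under a level of 4. CD24 passed over the list alone among stem cell and sphere genes (adjusted p = 0.953) at 0.26 (SE 0.061), where ALDH1A1 stood at -0.18 and NOTCH1 at 0.18. The invariant chain CD74 passed over the antigen presentation list alone at -0.33 (SE 0.083), with TAPBP at 0.15, TAP2 at 0.11 and PSMB8 at -0.092 not past it (list adjusted p = 0.694).

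Signalling and cell death lists gave no call. The integrin and focal adhesion list had a median of 0.014 (adjusted p = 0.534; FERMT1 at 0.13, ILK at 0.13) and the TGF-beta response list a mean of -0.019 (adjusted p = 0.616; TGFBR2 at 0.16). NOTCH pathway genes had a median of -0.007 (adjusted p = 0.676), with NRARP and HEY1 at -0.31 each. WNT pathway genes had a median of 0.024 (adjusted p = 0.694), with TCF7 at -0.18 and AXIN2 at 0.21. The p53 targets TP53I3 and CCNG1 stood at 0.14 and -0.12 (list median 0.008, adjusted p = 0.783). Apoptosis regulators had a median of -0.047 (adjusted p = 0.595), with BCL2L11 at 0.23 and BCL2L1 at 0.20.

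Metabolic and RNA lists did not pass either. ADM at 0.28 and VEGFA at -0.15 led the hypoxia and glycolysis genes (median -0.014, adjusted p = 0.543), and GLUL at 0.24 and PRODH the glutamine and amino acid genes (median -0.02, adjusted p = 0.616). CREB3L2 at 0.13 and DNAJB9 at -0.12 led the ATF4 and unfolded protein response genes (median -0.015, adjusted p = 0.616). STARD4 at -0.25 and INSIG1 at 0.23 led the cholesterol and fatty acid genes (median -0.019, adjusted p = 0.455). The small RNA machinery had a median of 0.003 (adjusted p = 0.901), with PRKRA at -0.25 and TUT7 at 0.18. Replication-dependent histone genes had a median of -0.019 (adjusted p = 0.543), with H3C10 at -0.63 (SE 0.23) and H2AC11 at 0.24.

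Markers of other cell types gave no list call, and most of their probe sets lay near background. Mean levels of the fibroblast, endothelial, blood and immune, and melanocyte lists lay between 2.97 and 3.73, with adjusted p of 0.616, 0.616, 0.300 and 0.783 and median changes of 0.022, 0.044, -0.006 and 0.027. Named members were PI16 at 0.21 and FBLN1 at 0.14, ROBO4 at 0.27 and CDH5 at 0.21, and SLC45A2 at 0.12 and KIT at 0.16. Of the blood and immune genes the lysosomal protein gene CD68 passed over the list alone at -0.21 (SE 0.053), at a level of 9.93, while ITGAM stood at -0.16, HBB at -0.15 and CD3E at 0.17. Camera's direction and the list median differed in sign for 7 lists without a call: mesenchymal (median 0.013), proteases (0.002), RAS family (0.003), stem cell (0.008), antigen presentation (0.012), p53 (0.008) and small RNA machinery (0.003). The mean of the differentiation list was 0.002 against a median of -0.016.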

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

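The tests of the LY6D region and of the AKR1 genes were chosen after the results were seen. So were the poly-A covariate as a setting and the lists compared below with random lists of matched level.

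Among 258 groups of 5 arrays tested, 11 had an array far from the other 4, where chance flags about 1 in 20 (12.9 expected). In called genes, VTCN1 in overexpressing replicate 2 stood at 6.19 against 5.75 to 5.87, and CXCL8 in overexpressing replicate 1 at 6.73 against 6.59 to 6.63; the gap of CXCL8 is small beside its change. List members with a distant control array were NEK2 in replicate 5 at 6.77 (others 6.87 to 6.88), MMP13 in replicate 2 at 11.59 (11.25 to 11.34), IFIH1 in replicate 1 at 6.80 (6.63 to 6.67) and ROBO4 in replicate 1 at 3.08 (3.52 to 3.69). Among overexpressing arrays, ILK stood at 8.72 in replicate 3 (8.54 to 8.58), CD24 at 10.76 in replicate 5 (10.56 to 10.61) and HBB at 2.25 in replicate 3 (2.35 to 2.36). The mitosis score of overexpressing replicate 1 was -0.0345 against 0.026 to 0.0486, and the blood and immune score of overexpressing replicate 4 was 0.0288 against -0.0379 to -0.0234.

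The 9 probe sets called between the labelled groups exceed what regrouping gave: 1 of 100 splits of the arrays into 5 and 5, the labelled one, called as many, and the highest other split called 1. For gene lists, 3 of 100 splits, the labelled one included, had as many past the threshold as the labels' 10. That share lies under 0.05, but the highest other split also had 10, so chance is not excluded for the count of lists. Lists of correlated genes such as the interferon-stimulated genes reached as small a camera p in 47 of 100 splits, and the mitosis list in 10. Epithelial junctions, NF-kB, ERK output, DNA replication and oxidative phosphorylation did so in 1, the labelled split, NRF2 targets and ribosomal proteins in 2 and YAP targets in 4.

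The NF-kB, ERK output and epithelial junction lists passed camera with the construct at its preset correlation, but at an adjusted p of 0.0599 each they did not with an estimated one. A trend of the change with signal level is argued against as the whole cause, since random lists matched on level did not shift as far. Their middle 95% (10000 lists) ran from -0.031 to 0.049 for NF-kB, -0.040 to 0.052 for ERK output and -0.033 to 0.035 for junctions. The mean change of 3 of the 3 lists lay outside it. These lists were picked for their camera result. Some lists without a call, such as proteases and invasion (mean -0.039, band -0.034 to 0.043), lay outside their bands too. Lying outside is therefore no separate evidence that a list moved. A labelling difference read by the poly-A spikes as the whole cause is argued against too, at the preset correlation only. With the spike mean as a covariate the largest camera adjusted p of the 3 was 0.0393. The mean changes went from -0.098 to -0.079 (NF-kB), from -0.093 to -0.087 (ERK output) and from 0.09 to 0.10 (junctions), with standard errors up to 0.027. The covariate was not run with an estimated correlation, and a labelling difference that the spikes do not read stays open. Drift between the separately established lines stays open and cannot be told apart from the microRNA, because 0 constructs have more than 1 labelled line. An effect of the microRNA is the biological explanation the design offers, and it stays open on the same ground.

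LY6D and the unnamed transcript antisense to it (probe set 17073247, chromosome 8, overlap 143866790 to 143868008) stood lower together, the antisense one by -0.85 with an adjusted p of 0.0657. A change of the whole neighbourhood is argued against, since the median of 15 neighbouring probe sets within 150 kb was 0.01 with a spread of 0.098 (MAD), and also 0.01 over the 5 of them above a level of 5. Signal of the LY6D strand read by antisense probes may account for the pair, as the antisense change exceeded that of LY6D by only -0.056 (SE 0.13); a real loss of both transcripts would look alike.

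The call of the NRF2 list depends on its AKR1 genes: without them the camera adjusted p was 0.283 and the mean change went from -0.074 to -0.022, while the median went only from -0.043 to -0.032 and 17 of the other 22 members were lower. Signal shared between these paralogs may therefore account for part of the call, but the test does not separate shared signal from a fall of AKR1 transcripts. The probe sets of AKR1C2 and AKR1C1, at mean levels of 3.41 and 3.82, lie near the antigenomic background of 3.37 to 3.40, so their differences decide nothing here. A biological fall of these enzymes stays open.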

How the results depend on the processing

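Alternatives with Student's test, cross-hybridization type 1, the poly-A covariate and the list without AKR1 genes were chosen after seeing the data; the others were planned. No call turned direction under any of them, 24 list directions changed among lists past the threshold in neither fit, and the cause of the shifts was not tested except where stated. The planned comparison of the authors' whole-series values with the series value table, and all seed site settings, were not run.

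The count of 9 probe sets (2 higher, 7 lower, 8 at 1.5-fold or more) became 39 (14 higher, 25 lower, 13 at 1.5-fold) with a trended robust prior, which kept all 9. It became 3 with Welch's test (0, 3 and 0), of which 1, ANXA10, was shared (chromosome 21 transcript 0.131, CXCL8 0.135, NRG1 0.175, MMP1 0.179, VTCN1 0.286, LY6D and CDH13 0.306, probe set 16673840 0.406), and 8 with Student's test (1 higher, 3 at 1.5-fold), of which 4 were shared (lost: LY6D 0.0705, NRG1 0.0964, CDH13 0.115, VTCN1 0.133, probe set 16673840 0.152). At adjusted p 0.01 it was 5 (0 higher, 4 at 1.5-fold). The poly-A covariate, correlated with the groups, gave 2 (0 higher, 2 lower, 2 at 1.5-fold). With that covariate the changes of the called genes stayed near their size (LY6D -0.79, MMP1 -0.78, CDH13 -0.55) and their standard errors grew 1.37- to 1.43-fold. With the replicate block it was 1 (0 higher, 1 lower, 1 at 1.5-fold), the chromosome 21 transcript. Replicate numbers do not pair the arrays, since deviations of same-numbered arrays correlated between -0.177 and 0.088 and 1 of 5 control arrays correlated best with its own number, so the replicate block spends degrees of freedom. Leaving out single arrays gave 5 to 8 calls (0 to 2 higher, 4 to 7 at 1.5-fold), with 5 without control replicate 2, 3 or 5 or overexpressing replicate 5. Counts were 8 to 13 under all other settings.

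RRAS2 stayed lower and short of the genome-wide threshold under every alternative (adjusted p 0.475 to 0.800; without single arrays -0.21 to -0.15). With the trended robust prior EREG (0.00314), FN1 (0.000247), CD68 (0.0110), CD24 (0.0160), NRAS (0.0164), CDH2 (0.0386) and TIMP2 (0.0434) passed, FN1 (0.0205) and CD68 (0.0339) also with Student's test. EREG also passed with median centring (0.0455), with symbols only (0.0384) and with cross-hybridization type 1 (0.0372). CDH13 was at 0.0507 with array weights.

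With an estimated correlation adjusted p was 0.0599 for junctions, NF-kB and ERK output, 0.174 for NRF2, 0.202 for oxidative phosphorylation, 0.342 for YAP and ribosomal proteins, 0.344 for DNA replication, 0.675 for mitosis and 0.730 for interferon. With fry it was 0.0787 for NRF2, 0.0830 for oxidative phosphorylation, 0.0906 for YAP, 0.101 for ribosomal proteins, 0.169 for DNA replication and for mitosis and 0.561 for interferon. The poly-A covariate gave 0.0752 for DNA replication and NRF2, 0.204 for mitosis, 0.361 for ribosomal proteins, 0.404 for oxidative phosphorylation and 0.709 for interferon, and NRF2 without AKR1 genes was at 0.283. Mitosis lost its call with the replicate block (0.0769) and median centring (0.0929); the block changed no other list call. Basal keratinocyte genes passed on ranks (0.0471), without dim probe sets (0.0446), with centring (0.0442), renewed quantiles (0.0453) and averaged probe sets (0.0495).

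Without single arrays, adjusted p ran from 0.00432 to 0.0716 for DNA replication (lost without control 1, 0.0716, or overexpressing 1, 0.0542), from 0.00856 to 0.156 for mitosis (lost without control 1 or 3 or overexpressing 2, 4 or 5), from 0.000924 to 0.889 for interferon (control 1 or 2, overexpressing 1 or 4), from 0.0131 to 0.0948 for NRF2 (control 1 or 2, overexpressing 1) and from 0.0192 to 0.113 for oxidative phosphorylation (control 1 or 4, overexpressing 4). Basal keratinocyte genes ran from 0.0150 to 0.209, reported miR-23 targets from 0.0488 to 0.401 and histones from 0.0433 to 0.848, passing in 4, 2 and 1 of 10. Junctions, NF-kB, ERK output, YAP and ribosomal proteins passed in 10 of 10. Probe sets near background, such as those of CCL2 and KRT1, limit what these arrays can show.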

Other observations

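The tests of the miR-23 target score, the annotation terms and the choice of the genes below came after the results were seen.

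Beyond the calls, several transcripts lay short of the limma threshold with groups fully apart. The noncoding RNA LINC02582 stood at 4.87 in controls and 3.58 in overexpressing cells, a difference of -1.29 (SE 0.19, adjusted p = 0.0657), the latter near background. MAL, a membrane raft protein of epithelia, was higher by 0.52 (SE 0.078, adjusted p = 0.0703), as was the estrogen sulfotransferase SULT1E1 by 0.48 (SE 0.072, 0.0708). The tryptophan-degrading enzyme KYNU at -0.52 (0.122), ALDH2 at -0.47 (0.164) and the activin subunit gene INHBB at 0.60 (0.164) followed. With a trended robust prior each of these 6 passed, at adjusted p of 0.0160, 0.00561, 0.00893, 0.0332, 0.0386 and 0.0332, together with the serine protease PRSS8 at 0.32 (0.0434) and the Arp2/3 subunit ARPC1A at -0.29 (0.00561).

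No neighbour of the called transcript on chromosome 21 passed the threshold. Within 150 kb the 10 other probe sets differed by -0.18 to 0.23, 8 of them at levels under 4, where a change would be hard to see. TMPRSS3, at a level of 5.17, counts among the 10 only because its annotated span, 38437942 to 43816955, covers the whole region. The unnamed probe set 16922804 stood at -0.18 (SE 0.076, limma adjusted p = 0.734), with an unadjusted p under 0.05. Its level of 2.36 lies under the antigenomic background of 3.37 to 3.40, so its difference decides nothing. The largest difference among the neighbours went the other way, ETS2-AS1 at 0.23 (SE 0.12). ETS2, which ends at 40196879 and encodes an ETS transcription factor, differed by 0.036 (SE 0.053, adjusted p = 0.935) at a level of 9.71. Over 1677 annotated biological process terms of 15 to 300 genes, camera called 0, by the estimated correlation also 0; ribosome biogenesis came closest, 61 of 86 genes lower (adjusted p = 0.0716; 0.988 with an estimated correlation), followed at 0.163 by transport from Golgi to plasma membrane, 21 of 23 genes higher.

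Of 65 distinct reporter probe sets for vector and viral sequences, the internal ribosome entry site read 11.84 ± 0.047 (SD, n = 5) in controls and 11.78 ± 0.044 in overexpressing cells. No untransduced cells were analysed here.

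A hypothesis for the reported miR-23 targets is repression by the overexpressed microRNA. Their score was 0.017 ± 0.023 (SD) in controls and -0.017 ± 0.034 in overexpressing cells, with an exact two-sided permutation p of 0.0794, so the arrays leave it open, and the test of seed sites that could decide was not run. For the YAP targets, culture density was not tested, since a score of the same members would only restate the list's call.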
